A study of Brassica rapa with 13 samples.

How the data were processed

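Cells were lysed and their DNA bisulfite-converted with the ZYMO EZ DNA Methylation-Gold kit, and libraries followed a published low-input bisulfite protocol, per the labels' protocols. Bisulfite turns unmethylated cytosines into bases read as T, so a cytosine read as C counts as methylated. Reads were trimmed with Trim Galore, per the submitters' processing notes. The aligner, its settings, the removal of duplicate reads and the genome build are not given in the sources used here. The 42 deposited files hold, for each sample and context, windows of 50 bp on 10 chromosomes with the fraction of calls that are methylated and, beside it, the authors' whole-number counts of methylated and unmethylated calls and of cytosine sites. In each window the deposited fraction equals the methylated count over all calls to within 5e-07, and the mean number of calls per site of a window was never under 5, which a minimum on sites or on windows would give. Calls are not independent molecules, since 1 read can give several calls and duplicates may remain, so SEs of single tiles cover the spread between calls and samples as modelled here and nothing else. Coordinates are those of the files, counted from 1.

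The K2 heat-treated sample came as 2 sets of files. The deeper set was used alone, because 96.5% of the CG windows of the shallower one are also in it, and the CG level over all calls was 48.2% in the deeper and 46.2% in the shallower set. The reference tables used here list genes of an assembly whose chromosome 9 ends at 45154914 by its last gene, short of the end of chromosome 9 in the files, so the builds differ. Gene bodies, promoters and the gene lists chosen beforehand were therefore not analysed here, and positions are given without gene names or annotation. No windows named as organelle or spike-in sequence were among those used, so no rate of non-conversion was estimated.

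Counts were summed into tiles of 500 bp. Levels are given in percent and differences in percentage points; a level over all calls is methylated calls over all calls of a sample. Tiles that met the coverage minimum in at least 1 sample in every context were classed by their mean level over the samples that met it: CHG-methylated (CHG at least 10%), CG-only (CHG under 5% and CG at least 20%), low (CG under 10% and CHG under 5%) and other. Levels of a class are means over those of its tiles covered in all contexts of all 13 samples, which number 53219, 2225, 13651 and 4908. Counts of called tiles by class take in every classed tile that was tested, so they rest on more tiles than the levels do. After the data were seen, chromosomes were also divided into bins of 1 Mb, called CHG-rich where at least 70% of tiles were CHG-methylated (81 bins) and CHG-poor where under 50% were (253 bins); tiles covered in at least 7 samples placed the bins. Differences of levels were tested with a two-sided exact permutation test. Its smallest p is 0.333 for 2 samples against 2 and also for 2 against 1, for which the design written beforehand gave a larger value in error.

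Single tiles were tested per context with a quasi-binomial model of the methylated and unmethylated counts, with the 7 groups as a factor and all 13 samples in 1 fit. Tiles needed 10 calls in CG and CHG and 20 in CHH in each sample of the groups compared. The dispersion of a tile was moderated across tiles by the squeezeVar method of limma, not allowed under 1, and used in an F test, which is two-sided, with Benjamini-Hochberg adjustment. A tile was called at an adjusted p under 0.05 and a difference of at least 30 points in CG, 20 in CHG and 10 in CHH. The heat-by-line test used the difference of the 2 heat differences in the same fit, K2 minus 49CX. Over all fitted tiles limma estimated infinite prior degrees of freedom for CG and CHG and 34.5 for CHH, so in CG and CHG 1 common dispersion was used. Many of these tiles have few residual degrees of freedom. With tiles of at least 5 residual degrees of freedom, called well-covered here, the prior degrees of freedom were 11.0, 20.7 and 6.90, so tiles could differ in their spread. That second prior was chosen after the data were seen, and its counts are printed beside those of the prior fixed beforehand.

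The model was tested on simulated data with the real depths and levels, 200 changed tiles per comparison and 1 dispersion for all tiles of a context, so this test cannot show excess calls from tiles that differ in their spread. For 49CX against K2 late microspores, 76.5% of tiles changed by 45 points in CG, 69.5% of those changed by 30 in CHG and 71.0% of those changed by 15 in CHH were recovered, with 5, 3 and 4 false calls. For embryos against the heat-treated sample the shares were 60.0%, 38.0% and 42.5%, with 18, 7 and 42 false calls. The port of squeezeVar was checked against limma itself. Each comparison was repeated on the other splits of its samples, of which 3 exist with the real one included.

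Named tiles follow a rule fixed before the data were examined: the 2 largest rises and 2 largest falls per context among called tiles whose replicates do not overlap between the groups. The text gives the largest rise and fall in CG, and in CHG and CHH the largest change in the direction with more calls; where a paragraph names fewer, they come from this list. In those tiles levels are calls pooled over replicates, and refits without 1 library, added after the data were seen, are given where they end the call or move the difference by over 1.5 times. Counts by adjusted p alone are given where they turn the balance of higher and lower calls. Runs of adjacent called tiles were looked at after the data were seen. Tiles whose mean CHH exceeds CHG by 10 points were left out of them, so such a tile could neither join nor bridge a run. Alternatives fixed beforehand were tiles of 1000 bp, the coverage minimum halved and doubled, a fit of only the groups compared, a replicate block, each replicate left out, the other file sets of the heat-treated sample, thinning to the total calls of the shallowest sample, unweighted windows, windows covered in all 13 samples and classes from leaves alone. Alternatives chosen after seeing the data were equal weights over those shared windows, the second prior, alone or with the replicate block, leaving out tiles whose mean CHH exceeds CHG by 10 points, and leaving out tiles over 10 times the median depth in any sample. The latter are 30412 CG, 31762 CHG and 30892 CHH tiles, which hold 44.9% to 68.5% of a sample's CG calls, so levels over all calls rest largely on them. Levels of CHG-methylated tiles do so too, since 33018 of those 53219 tiles are deep in at least 1 context and 20201 are not. The computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, R 4.3.3 and limma 3.58.1.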

Results

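DNA methylation was measured by whole-genome bisulfite sequencing in 13 samples of 2 lines of Brassica rapa, a crop of the cabbage family. Line K2 can be induced to androgenesis, the growth of embryos from immature pollen, and line 49CX cannot. K2 gave leaves, late unicellular microspores, pollen at the flowering stage and embryos, with 2 samples each, and 1 sample of microspores after heat shock. 49CX gave late unicellular microspores and microspores after heat shock, with 2 samples each. Plant DNA is methylated at cytosines in the CG, CHG and CHH contexts, where H is A, C or T, and methylation in all contexts is typical of transposons while CG methylation alone is typical of gene bodies. Each sample held from 13096398 CG calls (K2 leaf replicate 2) to 91672780 (K2 embryo replicate 1), from 15293291 to 103324011 CHG calls and from 46730034 to 311640057 CHH calls, 1 call being 1 cytosine read once. The windows spanned 364 Mb on 10 chromosomes, and 74003 of 727327 tiles of 500 bp (10.2%) met the coverage minimum in all contexts of all samples. The labels do not say that replicates came from separate plants or cultures, so p-values measure at most the spread between these samples, which may be technical. In CG and CHG, the prior fixed beforehand gave 1 common dispersion for all tiles. A tile's own spread between replicates therefore did not enter its p there. The library codes of the files also differ between groups: K2 heat-treated and embryo libraries share a code series, the other K2 libraries have another except leaf replicate 2, which has its own, and the 49CX libraries have a further one. If the code series mark library batches, which the labels do not say, batch and group cannot be told apart for K2 heat shock, for embryos against late microspores or leaves, or between the lines, and no value within a batch can be had there.

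Methylation in all 3 contexts was concentrated in 53219 of those covered tiles, which have a mean CHG level of at least 10% and are called CHG-methylated tiles here. Their CG level was 82.9% in K2 leaves, 80.7% in late microspores, 77.0% in the heat-treated sample, 88.8% in pollen and 84.1% in embryos. CHG in the same tiles was highest among the K2 groups in leaves at 27.3% and lowest in pollen at 19.0%. CHH was 7.26% in leaves, 7.18% in pollen and 7.75% in embryos, against 4.81% in late microspores and 4.97% in the heat-treated sample. In 49CX the CG, CHG and CHH levels were 79.0%, 20.8% and 5.17% in late microspores and 79.6%, 18.7% and 4.79% after heat shock. Across tiles, which are not independent replicates, replicates of a group had a median Pearson correlation of 0.984 for CG, 0.900 for CHG and 0.863 for CHH, and samples of different groups 0.965, 0.843 and 0.829. With 2 samples against 2 or 1, a two-sided exact permutation test cannot give a p under 0.333, so differences of levels are set beside the largest gap between replicates, and only single tiles could pass a threshold. For the levels of CHG-methylated tiles this smallest p was reached in each comparison except CHG of K2 heat shock, CHG of embryos against late or heat-treated microspores and CHH of embryos against leaves, whose values are given with them. Shared windows are those covered in all 13 samples, and deep tiles those over 10 times the median depth in any sample. Where an alternative setting or 1 left-out library moved a difference over all calls or in CHG-methylated tiles by over 1.5 times or turned its sign, its value is given.

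**Figure D1:**
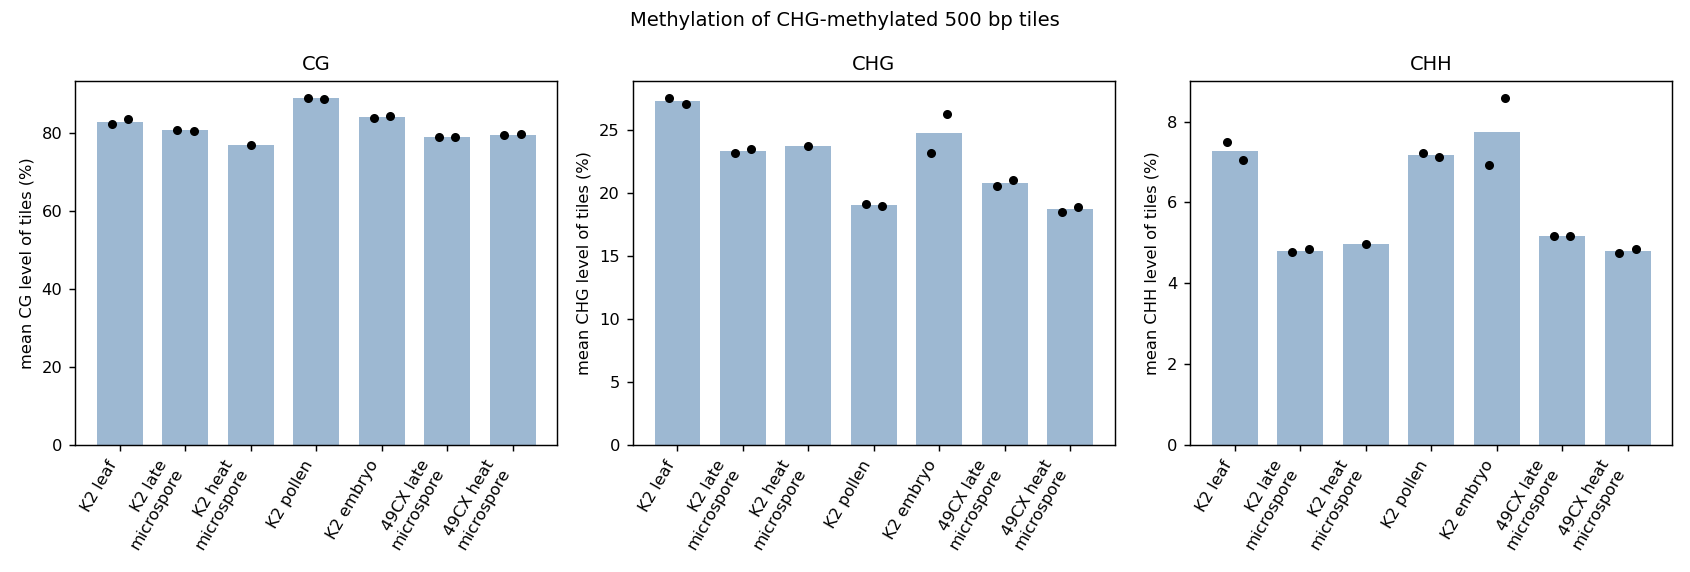
Mean methylation level (percent, vertical axis of each panel) of CHG-methylated tiles in the 7 groups, one panel per context; bars give the group mean and points the single samples. CG is highest in pollen at 88.8% and lowest in the heat-treated K2 sample at 77.0%.

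Late microspores were set against leaves to show how the methylome of the immature male gametophyte differs from that of a somatic tissue. CHG-methylated tiles held 23.4% ± 0.243 (SD, n = 2) CHG in late microspores and 27.3% ± 0.316 (SD, n = 2) in leaves, a difference of -3.93 points against a largest replicate gap of 0.447. CHH in these tiles was 4.81% ± 0.0516 (SD, n = 2) against 7.26% ± 0.317 (SD, n = 2), a difference of -2.45 points (gap 0.449), and CG differed by -2.24 points (gap 1.30). The CHG difference was negative on all 10 chromosomes, from -6.26 to -3.30 points. It was -10.4 points (gap 0.422) in the 4632 CHG-methylated tiles of chromosome bins where few tiles are CHG-methylated, and -3.18 points (gap 0.530) in the 47065 tiles of CHG-rich bins. Over all calls of the genome the differences were -4.49 points for CG, -3.38 for CHG and -1.93 for CHH, with gaps of 3.17, 0.528 and 0.151. The CG difference was -2.90 without K2 leaf replicate 2, -0.552 with windows weighted equally (overlapping groups), -7.17 over shared windows, -2.02 over shared windows weighted equally and -2.05 without deep tiles.

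Single tiles gave the same directions in the non-CG contexts. The model with limma's moderated dispersion called 1662 CHG tiles at an adjusted p under 0.05, 29 higher and 1633 lower in late microspores. Of the lower ones 1609 were CHG-methylated, a class that for single tiles takes in tiles not covered in all samples. The minimum CHG difference of a call largely sets this count, since a tile with little CHG in leaves cannot fall that far. The count therefore does not show where CHG changed. In CHH the model called 2395 tiles (349 higher and 2046 lower) and in CG 327 (116 higher and 211 lower). At 3011001 to 3011500 of chromosome 1, CG was higher in late microspores, 100% of 21 calls against 19.0% of 268 calls in leaves (SE of the difference 6.59 points, adjusted p = 0.00014, not called with the prior from well-covered tiles). Without K2 leaf replicate 1 the difference was 23.5 points (adjusted p = 0.78) and without K2 late microspore replicate 2 it was 81.0 points (adjusted p = 0.055), none of them a call. At 9867501 to 9868000 of chromosome 4, CG was lower in late microspores, 0% of 28 calls against 87.9% of 66 calls in leaves (SE of the difference 7.78 points, adjusted p = 1.6e-05). Without K2 leaf replicate 1 the difference was -40 points (adjusted p = 0.56), which is not a call. At 4407501 to 4408000 of chromosome 9, CHG was lower in late microspores, 22.8% of 57 calls against 84.6% of 39 calls in leaves (SE of the difference 11.6 points, adjusted p = 0.00088). Without K2 leaf replicate 1 the difference was -68.9 points (adjusted p = 0.1) and without K2 late microspore replicate 1 it was -41.8 points (adjusted p = 0.24), none of them a call. At 2324001 to 2324500 of chromosome 5, CHH was lower in late microspores, 0% of 80 calls against 81.8% of 1118 calls in leaves (SE of the difference 5.12 points, adjusted p = 0.0038, not called with the prior from well-covered tiles), in a tile where mean CHH exceeded mean CHG. Without K2 leaf replicate 1 the difference was -11.9 points (adjusted p = 0.83) and without K2 late microspore replicate 2 it was -81.8 points (adjusted p = 0.26), none of them a call. In CHG, 4 adjacent tiles at 23396001 to 23398000 of chromosome 1 held 18.4% CHG of 961 calls in late microspores against 44.5% of 1298 calls in leaves, 1 of 5 runs of that length. With a prior for the dispersion taken from well-covered tiles, chosen after seeing the data, 196, 1041 and 717 tiles were called in CG, CHG and CHH. The other splits of these 4 samples, too few for a share under 0.05, called at most 81, 181 and 549 tiles in CG, CHG and CHH with the prior from all tiles and 3, 5 and 2 with the second prior. Leaving out 1 library moved the count for CG to 621 without K2 leaf replicate 2. In CHG, 461 tiles were called without K2 leaf replicate 1 and 875 without K2 late microspore replicate 2. In CHH, 413 tiles were called without K2 leaf replicate 1, 3887 without K2 leaf replicate 2, 1555 without K2 late microspore replicate 1 and 587 without K2 late microspore replicate 2.

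Pollen against late microspores shows the later course of the same male lineage. CG in CHG-methylated tiles was 88.8% ± 0.0426 (SD, n = 2) in pollen and 80.7% ± 0.252 (SD, n = 2) in late microspores, a difference of 8.16 points (gap 0.356), and 94.1% of these tiles had more CG methylation in pollen. CHG had the opposite sign, with 23.4% ± 0.243 (SD, n = 2) in late microspores and 19.0% ± 0.110 (SD, n = 2) in pollen (-4.34 points, gap 0.343), while CHH was 7.18% ± 0.0707 (SD, n = 2) in pollen against 4.81% ± 0.0516 (SD, n = 2) (2.38 points, gap 0.10). All 10 chromosomes had these directions. The CG difference was 8.62 points (gap 0.339) in CHG-rich bins and 4.50 points (gap 0.509) in CHG-poor bins. The genome-wide differences were 4.28 points for CG (gap 1.46), -3.30 for CHG (gap 0.353) and 1.48 for CHH (gap 0.231), and for CG 2.64 with windows weighted equally, 7.16 over shared windows weighted equally and 2.17 without deep tiles.

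In pollen 520 CG tiles rose and 103 fell at an adjusted p under 0.05, 27 CHG tiles rose and 636 fell, and 1143 CHH tiles rose and 723 fell. Of the fallen CHG tiles, 630 were CHG-methylated, a count that the minimum CHG difference of a call again largely sets. Of the risen CG tiles, 234 had intermediate levels and 92 were of the class with little methylation. At 6330001 to 6330500 of chromosome 3, CG was higher in pollen, 96.3% of 162 calls against 11.2% of 313 calls in late microspores (SE of the difference 3.84 points, adjusted p = 2.2e-29). At 1819001 to 1819500 of chromosome 2, CG was lower in pollen, 0% of 21 calls against 83.3% of 30 calls in late microspores (SE of the difference 12.5 points, adjusted p = 0.00089). At 11275001 to 11275500 of chromosome 5, CHG was lower in pollen, 12% of 133 calls against 74.3% of 35 calls in late microspores (SE of the difference 11.4 points, adjusted p = 0.00018). Without K2 late microspore replicate 2 the difference was -54.6 points (adjusted p = 0.16) and without K2 pollen replicate 1 it was -54.3 points (adjusted p = 0.16), none of them a call. At 13928001 to 13928500 of chromosome 8, CHH was higher in pollen, 91.0% of 335 calls against 13.3% of 90 calls in late microspores (SE of the difference 11.1 points, adjusted p = 0.00074, not called with the prior from well-covered tiles), in a tile where mean CHH exceeded mean CHG. Without K2 late microspore replicate 2 the difference was 91.0 points (adjusted p = 0.11) and without K2 pollen replicate 1 it was 70 points (adjusted p = 0.2), none of them a call. Many CG rises lay in very deep tiles: without tiles over 10 times the median depth in any sample, a limit chosen after seeing the data, 344 CG tiles were called, 244 higher and 100 lower. Counts with the prior from well-covered tiles were 567, 212 and 625 in CG, CHG and CHH. Other splits of the 4 samples, again too few for a share under 0.05, reached at most 5, 9 and 255 tiles with the first prior and 0, 0 and 1 with the second. Without 1 library the count changed for CG to 947 without K2 late microspore replicate 1. In CHG, 369 tiles were called without K2 late microspore replicate 2 and 396 without K2 pollen replicate 1. In CHH, 684 tiles were called without K2 late microspore replicate 2 and 2905 without K2 embryo replicate 1 or without K2 embryo replicate 2.

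Heat shock is the treatment that starts androgenesis in K2, and 1 sample of heat-treated K2 microspores was compared with the 2 of untreated late microspores. CHG-methylated tiles held 77.0% CG after heat shock against 80.7% ± 0.252 (SD, n = 2) before, a difference of -3.65 points against a gap of 0.356 between the untreated replicates. In the 31811 of these tiles that both of the sample's sequencing sets covered, CG was 76.2% in the deeper set, the one used, and 76.4% in the shallower. Over windows with at least 20 calls in both sets it was 46.2% and 43.1%. Both sets are of 1 sample and may not be independent. CG-only tiles, methylated in CG but hardly in CHG, held 34.8% against 37.2% ± 0.286 (SD, n = 2), a difference of -2.47 points (gap 0.405). The CG difference was -3.95 points (gap 0.339) in CHG-rich bins and -1.11 (gap 0.509) in CHG-poor bins, and it was negative on all 10 chromosomes (-6.07 to -0.593 points). CHG in CHG-methylated tiles was 23.8% against 23.4% ± 0.243 (SD, n = 2) (0.415 points, gap 0.343, two-sided exact permutation p = 0.667), a difference of 2.23 points in CHG-poor bins (gap 0.422) and 0.199 in CHG-rich bins (gap 0.319). Over all of these tiles it was 0.244 without K2 late microspore replicate 1 and 0.655 without deep tiles. CHH there differed by 0.166 points (gap 0.0730) and by 0.331 without deep tiles and -0.0179 with the shallower set. Over all calls the differences were -4.23, -0.669 and -0.0771 points for CG, CHG and CHH (gaps 0.788, 0.353 and 0.0349). For CG the value was -2.45 over shared windows. For CHG it was -1.02 with windows weighted equally, 0.0609 over shared windows (overlapping groups), 0.134 over shared windows weighted equally, -1.01 without deep tiles and -1.27 with the shallower set, and for CHH -0.192 with windows weighted equally, 0.124 over shared windows, 0.0840 over shared windows weighted equally, -0.326 without deep tiles, -0.0309 without tiles whose mean CHH exceeds CHG by 10 points and -0.195 with the shallower set.

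Among single tiles, heat shock in K2 went with 653 called CG tiles, 227 higher and 426 lower. Of 77013 CHG-methylated tiles tested, 178 (0.231%) were lower and 45 (0.0584%) higher. Of 5353 CG-only tiles tested, 156 (2.91%) were lower and 97 (1.81%) higher. CHG had 221 called tiles (160 higher and 61 lower) and CHH 480 (215 higher and 265 lower). At 7094501 to 7095000 of chromosome 2, CG was higher in the heat-treated K2 sample, 100% of 13 calls against 0% of 35 calls in K2 late microspores (SE of the difference 8.98 points, adjusted p = 0.00034, not called with the prior from well-covered tiles), in a tile where mean CHH exceeded mean CHG. At 40615001 to 40615500 of chromosome 6, CG was lower in the heat-treated K2 sample, 0% of 17 calls against 100% of 27 calls in K2 late microspores (SE of the difference 7.71 points, adjusted p = 0.00021). At 32152001 to 32152500 of chromosome 2, CHG was higher in the heat-treated K2 sample, 90.9% of 11 calls against 6.38% of 94 calls in K2 late microspores (SE of the difference 14.7 points, adjusted p = 0.0086, not called with the prior from well-covered tiles). Without K2 late microspore replicate 2 the difference was 85.6 points (adjusted p = 0.13), which is not a call. At 18676501 to 18677000 of chromosome 2, CHH was lower in the heat-treated K2 sample, 0% of 64 calls against 90.5% of 95 calls in K2 late microspores (SE of the difference 6.27 points, adjusted p = 0.00023, not called with the prior from well-covered tiles), in a tile where mean CHH exceeded mean CHG. The treated group has 1 sample, whose spread was taken to be that of the other groups. The prior from well-covered tiles left 400, 19 and 11 calls in CG, CHG and CHH, and the shallower sequencing set of the treated sample gave 194, 35 and 27. Splits with another of the 3 samples alone, too few for a share under 0.05, called up to 179, 35 and 459 tiles with the first prior and 0, 0 and 3 with the second. Refits without 1 library moved the count for CHG to 131 without K2 late microspore replicate 1, 98 without K2 late microspore replicate 2 and 412 without K2 embryo replicate 1 or without K2 embryo replicate 2. In CHH, 1478 tiles were called without K2 embryo replicate 1 or without K2 embryo replicate 2.

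In the non-inducible line 49CX, 2 heat-treated samples were compared with 2 untreated ones. CHG in CHG-methylated tiles was 18.7% ± 0.247 (SD, n = 2) after heat shock and 20.8% ± 0.299 (SD, n = 2) before, a difference of -2.10 points (gap 0.423) that was negative on all 10 chromosomes. CG in these tiles was 79.6% ± 0.225 (SD, n = 2) against 79.0% ± 0.0639 (SD, n = 2), a difference of 0.592 points (gap 0.319), and CHH 4.79% ± 0.0669 (SD, n = 2) against 5.17% ± 0.0107 (SD, n = 2), a difference of -0.381 points (gap 0.0946). CG-only tiles differed by 0.198 points in CG, less than the gap of 0.436. Over all calls CHG differed by -1.96 points (gap 0.646) and CHH by -0.212 (gap 0.0900). CG differed by -0.815 points, within its gap of 2.43, and by -0.439 without 49CX late microspore replicate 2, 0.398 without 49CX heat microspore replicate 1, -2.03 without 49CX heat microspore replicate 2, 0.177 over shared windows, 0.543 over shared windows weighted equally and -1.75 without deep tiles. The CHH difference was -0.330 over shared windows weighted equally. The model called 30 CG tiles (17 higher and 13 lower), 98 CHG tiles (18 higher and 80 lower) and 885 CHH tiles (540 higher and 345 lower). At 42861001 to 42861500 of chromosome 9, CHG was lower in heat-treated 49CX microspores, 33.3% of 81 calls against 100% of 23 calls in 49CX late microspores (SE of the difference 8.59 points, adjusted p = 0.01, not called with the prior from well-covered tiles). Without 49CX late microspore replicate 1 the difference was -66.7 points (adjusted p = 0.25), without 49CX late microspore replicate 2 it was -66.7 points (adjusted p = 0.24) and without 49CX heat microspore replicate 1 it was -68.4 points (adjusted p = 0.066), none of them a call. At 20927001 to 20927500 of chromosome 9, CHH was higher in heat-treated 49CX microspores, 88.6% of 185 calls against 1.68% of 119 calls in 49CX late microspores (SE of the difference 6.79 points, adjusted p = 0.00027, not called with the prior from well-covered tiles), in a tile where mean CHH exceeded mean CHG. Without 49CX late microspore replicate 1 the difference was 82.0 points (adjusted p = 0.098), which is not a call. With the prior from well-covered tiles, limma's moderated dispersion left 0 CG, 0 CHG and 6 CHH calls. Of the 189376 CG and 202867 CHG tiles tested with it, 9099 and 13130 had an unadjusted p under 0.05 in the F test. Other splits of the 4 samples, too few for a share under 0.05, called at most 38, 6 and 1079 tiles with the first prior, more than the real groups in CG and CHH, and 1, 0 and 9 with the second. Omitting 1 library moved the count for CG to 1.0e+02 (rounded to 2 digits) without K2 embryo replicate 1 or without K2 embryo replicate 2. In CHG, 202 tiles were called without K2 embryo replicate 1 or without K2 embryo replicate 2, 35 without 49CX late microspore replicate 1, 42 without 49CX late microspore replicate 2, 28 without 49CX heat microspore replicate 1 and 59 without 49CX heat microspore replicate 2. In CHH, 2595 tiles were called without K2 embryo replicate 1 or without K2 embryo replicate 2 and 1361 without 49CX heat microspore replicate 2.

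Whether the heat difference itself differed between the lines was tested with an interaction term, K2 minus 49CX. It passed in 621 CG tiles, of which 441 had the lower heat difference in K2 and 180 the higher one. In CHG, 355 tiles passed (297 higher and 58 lower in K2), and in CHH 793 (228 and 565). The K2 heat arm of this test is 1 sample, whose spread was taken from the other groups and whose library code series differs from that of its untreated samples, so the term rests on that library. In CHG-methylated tiles the heat differences were -3.65 points of CG in K2 and 0.592 in 49CX, and 0.415 points of CHG in K2 and -2.10 in 49CX. The prior from well-covered tiles gave 381, 23 and 46 tiles in CG, CHG and CHH. Dropping 1 library moved the count for CHG to 641 without K2 embryo replicate 1 or without K2 embryo replicate 2, 229 without 49CX late microspore replicate 1, 218 without 49CX late microspore replicate 2 and 183 without 49CX heat microspore replicate 1. In CHH, 1919 tiles were called without K2 embryo replicate 1 or without K2 embryo replicate 2.

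Embryos grown from K2 microspores were compared with the late microspores, with the heat-treated sample and with leaves. Against late microspores, CHG-methylated tiles held 84.1% ± 0.271 (SD, n = 2) CG in embryos and 80.7% ± 0.252 (SD, n = 2) in late microspores, a difference of 3.37 points (gap 0.383), and 7.75% ± 1.16 (SD, n = 2) CHH against 4.81% ± 0.0516 (SD, n = 2), a difference of 2.94 points (gap 1.64). Both were positive on all 10 chromosomes. The CHH difference was 5.32 points in CHG-poor bins (gap 3.05) and 2.65 in CHG-rich bins (gap 1.47). CHG was 24.8% ± 2.19 (SD, n = 2) in embryos, whose replicates lay 3.10 points apart, against 23.4% ± 0.243 (SD, n = 2). That difference of 1.41 points did not separate the groups (two-sided exact permutation p = 0.667) and was 2.95 without K2 embryo replicate 1 and -0.142 without K2 embryo replicate 2. Over all calls the differences were 7.49 points for CG, 1.86 for CHG and 2.57 for CHH (gaps 0.788, 2.31 and 1.36). In CG the value was -1.69 with windows weighted equally, 3.03 over shared windows weighted equally and 2.68 without deep tiles, so the sign turned with each sample's own windows and not with shared ones. In CHG it was 3.01 without K2 embryo replicate 1, 0.701 without K2 embryo replicate 2, -0.503 with windows weighted equally (overlapping groups) and 1.04 over shared windows weighted equally (overlapping groups).

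Between embryos and late microspores 3391 CHH tiles rose and 878 fell. Of the rises, 2253 lay in CHG-methylated tiles, which is 2.39% of those tested. The share was 2.49% in tiles of intermediate level, 1.54% in low, 1.44% in CG-only and 3.16% in unclassed tiles. CG tiles rose in 840 and fell in 585 cases, most often in CG-only tiles (328 and 316), and CHG tiles in 563 and 423. At 9867501 to 9868000 of chromosome 4, CG was higher in embryos, 97.3% of 112 calls against 0% of 28 calls in late microspores (SE of the difference 4.81 points, adjusted p = 3e-09). At 4255501 to 4256000 of chromosome 1, CG was lower in embryos, 0.935% of 107 calls against 97.4% of 38 calls in late microspores (SE of the difference 5.41 points, adjusted p = 2.9e-11). At 5689001 to 5689500 of chromosome 4, CHG was higher in embryos, 62.7% of 59 calls against 0% of 117 calls in late microspores (SE of the difference 9.02 points, adjusted p = 5.5e-10), in a tile where mean CHH exceeded mean CHG. Without K2 embryo replicate 2 the difference was 33.3 points (adjusted p = 0.0033). At 23641001 to 23641500 of chromosome 2, CHH was higher in embryos, 90.7% of 964 calls against 4.55% of 88 calls in late microspores (SE of the difference 4.17 points, adjusted p = 5.7e-09). In CG, 4 adjacent tiles at 26520001 to 26522000 of chromosome 3 held 94.7% CG of 1598 calls in embryos against 6.96% of 230 calls in late microspores, 1 of 2 runs of that length. Under the prior from well-covered tiles the totals of 1425 CG, 986 CHG and 4269 CHH calls became 1141, 568 and 2015. Splits of the 4 samples other than the real one, too few for a share under 0.05, called up to 680, 245 and 2501 tiles under the first prior and 125, 14 and 80 under the second. Refits with 1 library fewer moved the count for CG to 2175 without K2 late microspore replicate 1. In CHG, 449 tiles were called without K2 late microspore replicate 2 and 1791 without K2 embryo replicate 1. In CHH, 1224 tiles were called without K2 late microspore replicate 2 and 8026 without K2 embryo replicate 1.

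Against the heat-treated K2 sample, embryos held more CG methylation in CHG-methylated tiles, 84.1% ± 0.271 (SD, n = 2) against 77.0%, a difference of 7.02 points (gap 0.383), and in CG-only tiles, 37.9% ± 0.287 (SD, n = 2) against 34.8% (3.18 points, gap 0.407). CHH in CHG-methylated tiles was 7.75% against 4.97%, a difference of 2.78 points (gap 1.64). CHG differed by 0.991 points, under the gap of 3.10 between the embryo replicates (two-sided exact permutation p = 1.0), and by 2.54 without K2 embryo replicate 1 and -0.558 without K2 embryo replicate 2. Over all calls the differences were 11.7, 2.53 and 2.65 points for CG, CHG and CHH (gaps 0.360, 2.31 and 1.36). They became, for CG, 4.34 with windows weighted equally and 6.42 over shared windows weighted equally, and for CHG 1.37 without K2 embryo replicate 2, 0.519 with windows weighted equally (overlapping groups) and 0.905 over shared windows weighted equally (overlapping groups). Of 1787 called CG tiles 1292 were higher and 495 lower in embryos, of 2657 CHG tiles 640 were higher and 2017 lower, and of 3445 CHH tiles 2525 were higher and 920 lower. By adjusted p alone, without the minimum difference, the balance in CHG turned, with 6046 higher and 4684 lower in embryos. At 55510001 to 55510500 of chromosome 9, CG was higher in embryos, 99.1% of 109 calls against 0% of 12 calls in the heat-treated sample (SE of the difference 9.22 points, adjusted p = 1.2e-05). At 36578001 to 36578500 of chromosome 9, CHG was lower in embryos, 11.9% of 42 calls against 100% of 10 calls in the heat-treated sample (SE of the difference 11.9 points, adjusted p = 0.0033). In CHH, 10 adjacent tiles at 36514501 to 36519500 of chromosome 1 held 62.8% CHH of 98443 calls in embryos against 33.2% of 9983 calls in the heat-treated sample, the longest run of adjacent called tiles in this context. These tiles are deep: the median tile held 285 and 278 CHH calls in embryos and 146 in the heat-treated sample. Their depth exceeded the median by a larger factor in embryos, and its bearing on the level was not tested. With the second prior 1416, 1531 and 561 tiles were called, and with the shallower sequencing set of the heat-treated sample 727, 765 and 110. Splits setting 1 embryo library alone, too few for a share under 0.05, called up to 1777, 803 and 6438 tiles with the first prior. With the second they called up to 277, 47 and 2456. The CHH counts exceed those of the real groups with either prior, so the 2 embryo libraries differed from each other in CHH. In CG with the first prior these splits called at least 1743 tiles, close to the 1787 of the real groups. Single omissions moved the count for CG to 3039 without K2 embryo replicate 1 and 3023 without K2 embryo replicate 2. In CHG, 4055 tiles were called without K2 embryo replicate 2. In CHH, 8585 tiles were called without K2 embryo replicate 1 and 5220 without K2 embryo replicate 2.

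Embryos and leaves, both sporophytic tissues of K2, were close in CG and CHH of CHG-methylated tiles. CG was 84.1% ± 0.271 (SD, n = 2) in embryos and 82.9% ± 0.917 (SD, n = 2) in leaves, a difference of 1.12 points that was smaller than the gap of 1.30 between replicates and became 0.475 without K2 leaf replicate 1 and 1.77 without K2 leaf replicate 2. CHH differed by 0.490 points with overlapping groups (gap 1.64, two-sided exact permutation p = 1.0), and by 0.266 without K2 leaf replicate 2, 1.31 without K2 embryo replicate 1, -0.330 without K2 embryo replicate 2 and 0.823 without deep tiles. CHG was 24.8% against 27.3%, a difference of -2.53 points within the gap of 3.10, or -0.980 without K2 embryo replicate 1 and -4.08 without K2 embryo replicate 2. In CHG-poor bins the CHG difference was -9.30 points, over the gap of 6.81 there, and in CHG-rich bins -1.79 points, under its gap of 2.64. Over all calls CG differed by 3.0 points (gap 3.17), CHG by -1.53 (gap 2.31) and CHH by 0.641 (gap 1.36). The CG value was 1.42 without K2 leaf replicate 1, 4.59 without K2 leaf replicate 2, -2.24 with windows weighted equally (overlapping groups), 1.01 over shared windows weighted equally and 0.628 without deep tiles, so shared windows kept its sign. The difference in CHG was -0.369 without K2 embryo replicate 1, -2.68 without K2 embryo replicate 2 and -3.12 with windows weighted equally, and in CHH 1.32 without K2 embryo replicate 1, -0.0380 without K2 embryo replicate 2, 0.387 with windows weighted equally, 0.385 over shared windows and 0.333 over shared windows weighted equally. In single tiles, 3720 CHG tiles fell and 111 rose in embryos relative to leaves. Falls were called in 2769 of 53939 tested tiles (5.13%) of CHG-poor bins and 508 of 67680 (0.751%) of CHG-rich bins. In the remaining bins they were 443 of 6790 (6.52%). A tile with little CHG in leaves cannot fall by the minimum difference of a call, so these counts alone do not show where CHG changed. CG tiles rose in 414 and fell in 466 cases, and CHH tiles in 997 and 788. With no minimum difference the balance in CG turned to 4223 higher and 2576 lower at the same adjusted p. At 39912501 to 39913000 of chromosome 5, CG was higher in embryos, 96.5% of 86 calls against 3.28% of 61 calls in leaves (SE of the difference 5.36 points, adjusted p = 5e-12). At 41257001 to 41257500 of chromosome 9, CG was lower in embryos, 0% of 182 calls against 98.1% of 312 calls in leaves (SE of the difference 1.46 points, adjusted p = 3.3e-47). At 162501 to 163000 of chromosome 10, CHG was lower in embryos, 6.35% of 63 calls against 79.5% of 44 calls in leaves (SE of the difference 9.89 points, adjusted p = 5.3e-07). At 37302001 to 37302500 of chromosome 9, CHH was higher in embryos, 83.4% of 319 calls against 7.45% of 2053 calls in leaves (SE of the difference 3.52 points, adjusted p = 1.4e-15). This tile held fewer calls in embryos, while the median tile held 285 and 278 CHH calls in the embryo samples and 278 and 91 in leaves. Whether reads of other copies entered it was not tested, so the higher level is not read as a gain of CHH methylation. In CHG, 7 adjacent tiles at 9993001 to 9996500 of chromosome 7 held 26.2% CHG of 8792 calls in embryos against 57.8% of 4047 calls in leaves, the longest run of its kind. The second prior gave 803, 3572 and 549 calls in CG, CHG and CHH. Other splits, too few for a share under 0.05, gave at most 492, 820 and 2181 with the first prior and 101, 0 and 397 with the second. In CHH with the first prior they called at least 1812 tiles, more than the 1785 of the real groups. Counts without 1 library moved for CG to 584 without K2 leaf replicate 1 and 3848 without K2 leaf replicate 2. In CHG, 1639 tiles were called without K2 leaf replicate 1, 10029 without K2 leaf replicate 2, 2421 without K2 embryo replicate 1 and 6104 without K2 embryo replicate 2. In CHH, 493 tiles were called without K2 leaf replicate 1, 5795 without K2 leaf replicate 2, 3184 without K2 embryo replicate 1 and 3096 without K2 embryo replicate 2.

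The lines were compared in untreated late microspores, before any heat shock. In 49CX, CHG-methylated tiles held 20.8% ± 0.299 (SD, n = 2) CHG against 23.4% ± 0.243 (SD, n = 2) in K2, a difference of -2.55 points (gap 0.423), and 79.0% ± 0.0639 (SD, n = 2) CG against 80.7% ± 0.252 (SD, n = 2), a difference of -1.68 points (gap 0.356). CHH was 5.17% ± 0.0107 (SD, n = 2) against 4.81% ± 0.0516 (SD, n = 2) (0.364 points, gap 0.0730). The CHG difference was -2.88 points (gap 0.423) in CHG-rich bins and 0.212 (gap 0.422) in CHG-poor bins. CG-only tiles held 33.8% ± 0.148 (SD, n = 2) CG in 49CX and 37.2% ± 0.286 (SD, n = 2) in K2, a difference of -3.46 points (gap 0.405). Over all calls the differences were 6.72 points for CG, 0.0196 for CHG and 0.487 for CHH (gaps 0.788, 0.406 and 0.0459). The difference in CG was -1.16 with windows weighted equally (overlapping groups), -1.01 over shared windows weighted equally and 2.11 without deep tiles, so its sign turned with equal weights also over shared windows. The CHG value, under its gap, was -0.157 without K2 late microspore replicate 1, 0.196 without K2 late microspore replicate 2, 0.223 without 49CX late microspore replicate 1, -0.183 without 49CX late microspore replicate 2, -1.51 with windows weighted equally, -0.126 over shared windows, -2.29 over shared windows weighted equally and -0.381 without deep tiles. That in CHH was 0.221 with windows weighted equally and 0.270 over shared windows weighted equally.

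Calls between the lines depended on the minimum difference. With it, the model called 1897 CG tiles (905 higher and 992 lower in 49CX), 828 CHG tiles (425 higher and 403 lower) and 883 CHH tiles (374 higher and 509 lower). By adjusted p alone, CHG tiles were mainly lower in 49CX (816 higher and 2611 lower), while CG had 2477 higher and 2216 lower and CHH 614 higher and 586 lower. Of the 5085 CG-only tiles tested in CG, a wider set than those covered in all samples, 380 (7.47%) were higher and 596 (11.7%) lower in 49CX. At 12144001 to 12144500 of chromosome 6, CG was higher in 49CX, 99.0% of 98 calls against 0% of 65 calls in K2 (SE of the difference 2.67 points, adjusted p = 3.6e-16). At 12363001 to 12363500 of chromosome 6, CG was lower in 49CX, 2.38% of 84 calls against 100% of 25 calls in K2 (SE of the difference 5.39 points, adjusted p = 8.2e-08). At 17524001 to 17524500 of chromosome 3, CHG was higher in 49CX, 80.3% of 76 calls against 0.980% of 102 calls in K2 (SE of the difference 6.77 points, adjusted p = 1.6e-13). At 2417001 to 2417500 of chromosome 8, CHH was lower in 49CX, 0.855% of 117 calls against 89.5% of 190 calls in K2 (SE of the difference 5.93 points, adjusted p = 3.3e-05, not called with the prior from well-covered tiles), in a tile where mean CHH exceeded mean CHG. In CG, 4 adjacent tiles at 28495001 to 28497000 of chromosome 1 held 17.3% CG of 1378 calls in 49CX against 63.9% of 784 calls in K2, the longest such run. A prior from well-covered tiles gave 1333, 364 and 35 calls in CG, CHG and CHH. Other splits of the 4 samples, too few for a share under 0.05, gave at most 29, 3 and 390 calls with the first prior and 0, 0 and 5 with the second. The count without 1 library moved for CHG to 383 without K2 late microspore replicate 2, 425 without 49CX late microspore replicate 1 and 538 without 49CX late microspore replicate 2. In CHH, 582 tiles were called without K2 late microspore replicate 2 and 2067 without K2 embryo replicate 1 or without K2 embryo replicate 2.

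**Figure D2:**
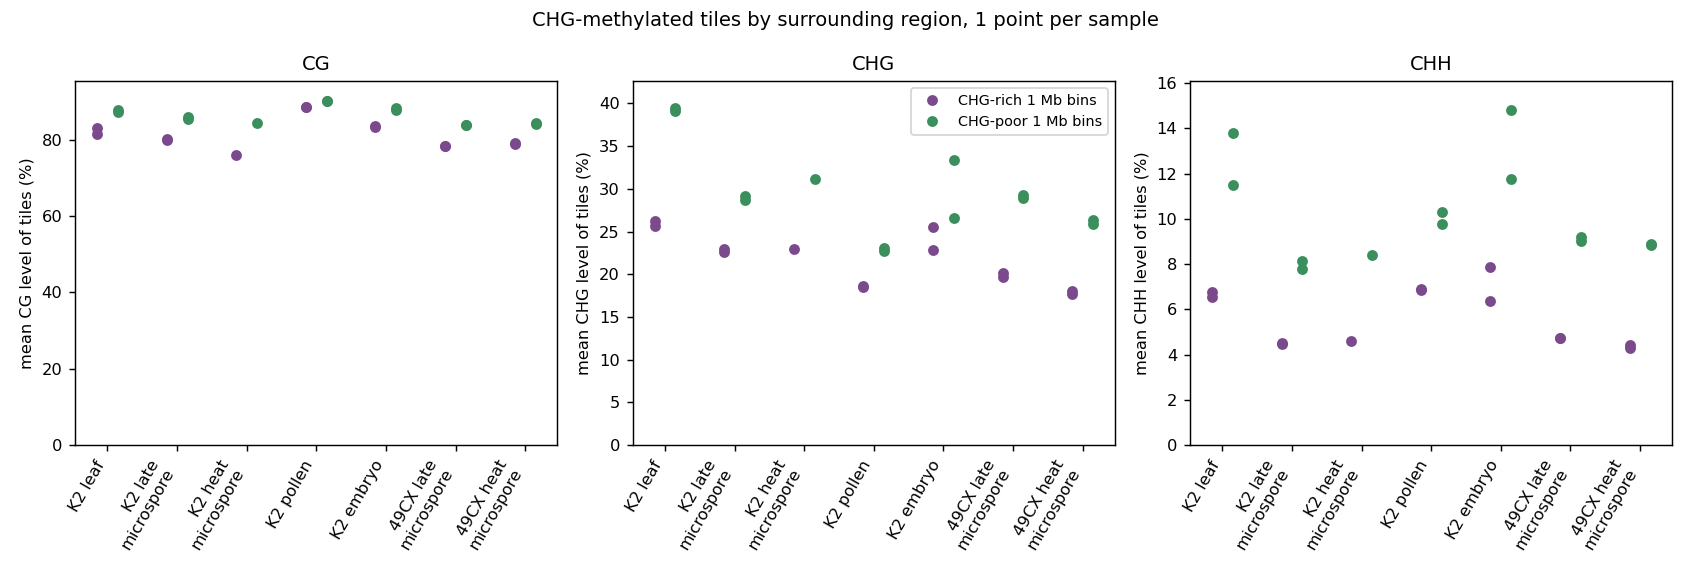
Methylation level (percent, vertical axis) of CHG-methylated tiles in CHG-rich and CHG-poor chromosome bins of 1 Mb, one panel per context and one point per sample. CHG in CHG-poor bins is 39.3% in leaves and 28.9% in K2 late microspores, and in CHG-rich bins 25.9% and 22.8%.

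**Figure D3:**
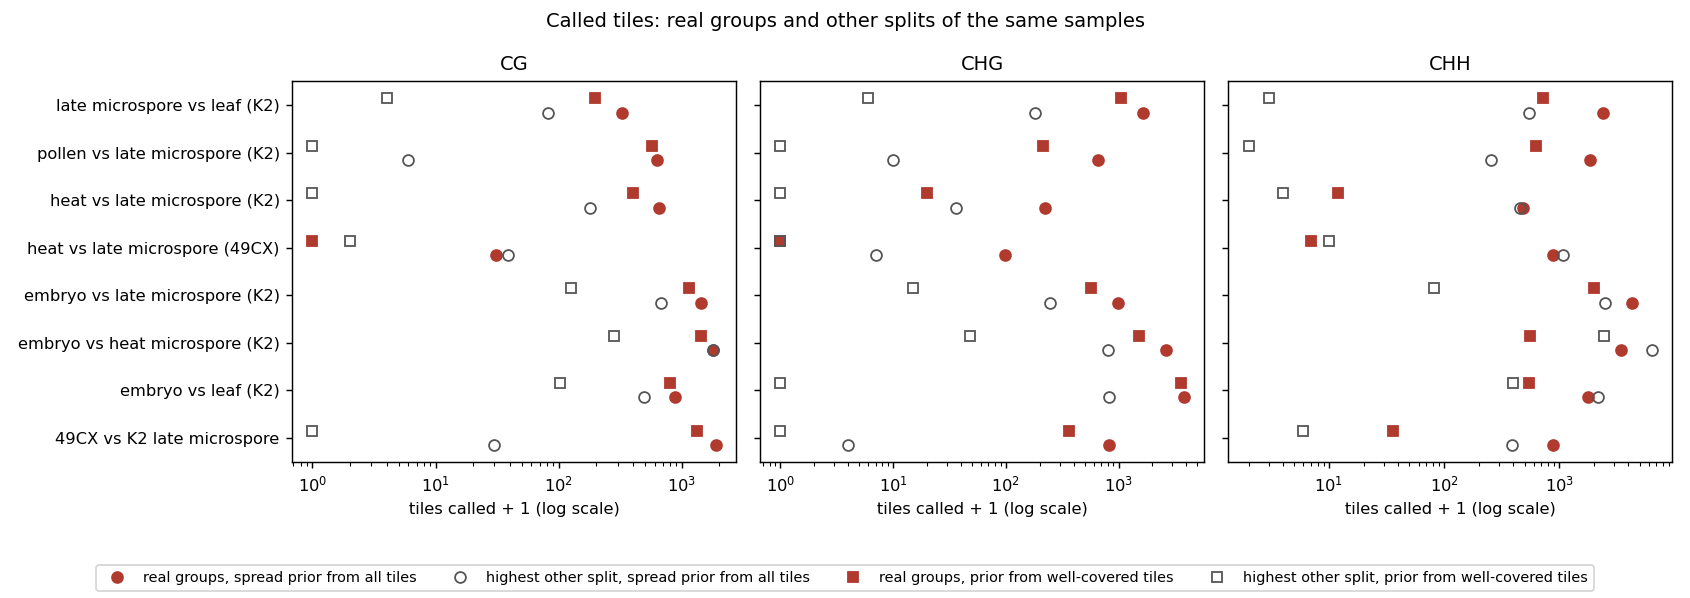
Number of called tiles plus 1 (log axis) per comparison, one panel per context; filled symbols are the real groups and open symbols the highest count of the other splits, with circles for the prior from all tiles and squares for the prior from well-covered tiles. For CG of 49CX against K2 late microspores the real groups gave 1897 and 1333 calls and the other splits at most 29 and 0.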

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

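All tests of explanations in this part were chosen after the results were seen, while the heat-by-line test was planned. The heat difference of K2 differed from that of 49CX by the interaction test in 621 CG tiles, 355 CHG tiles and 793 CHH tiles; with the prior from well-covered tiles these counts were 381, 23 and 46. The K2 heat arm of this test has 1 library, of another code series than its untreated samples, so a difference of that library cannot be told apart from one between the lines.

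The first pattern is the lower CG in the K2 heat-treated sample, -3.65 points in CHG-methylated tiles. A general loss of methylated calls would take the same share from CHG, -1.06 points, but CHG differed by 0.415 points (gap 0.343), so such a loss is argued against as the whole cause in these tiles, and a smaller one stays open. The sample's 2 file sets did differ by a like share in every context over windows with at least 20 calls in both (CG 46.2% and 43.1%, CHG 15.9% and 14.9%, CHH 4.80% and 4.47%). In the 34256 CHG-methylated tiles both cover, CHG was 0.305 points above late microspores in the deeper and 0.297 in the shallower set (gap 0.334). Neither lay near -1.06 points, but both sets are of 1 sample. In 92.4% of shared CHG windows the shallower counts fit within the deeper ones, so the sets may not be independent. Over all calls without deep tiles, the differences were negative in each context, -6.27 (CG), -1.01 (CHG) and -0.326 points (CHH). Samples cover differing windows there, and over windows covered in all samples CHG was 17.4% against 17.3% in late microspores. Outside the CHG-methylated tiles a general loss therefore stays open. Total depth is argued against too, since 602 CG tiles were called at equal total calls against 653, though depth per tile was not made equal. A library batch alone, with no effect of stage, would lower the embryo libraries of the same code series too, which lay 3.37 points above late microspores; since their stage differs, a batch together with an effect of stage stays open and cannot be told apart from the treatment, and an effect of heat shock, which the design names, stays open too, on 1 treated sample.

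The second pattern is the higher CHH of embryos, 2.94 points above late microspores in CHG-methylated tiles. Incomplete conversion would raise CHH at least as much in tiles with little methylation, where the difference was 0.833 points, under the bound set for it, so it cannot be the whole cause. A single embryo library is argued against, since embryo replicate 1 alone lay 2.12 points above late microspores, over the gap of 1.64. The code series of the embryo libraries differs from that of late microspores. A batch alone, with no effect of heat shock, would raise the heat-treated sample of the same series as much. Embryos lay 2.78 points above it (gap 1.64 between the embryo replicates). That sample is 1 library without a spread of its own, so this does not decide the question. A batch, alone or together with an opposite effect of heat shock, stays open, as does the developmental stage as a candidate explanation.

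The third pattern is the set of 1897 CG tiles that differ between the lines. Sequence variants at CG sites alone would leave CHG in the same tiles without a matching difference. CHG was 5.34 points higher (SE over tiles 0.378) in 791 tiles with higher CG. It differed by -3.22 points (SE 0.287) in 842 tiles with lower CG, and the 2 values lie 8.56 points apart. Variants at CG sites alone are therefore argued against as the cause of the whole set. Tiles are not independent replicates, so these SEs do not cover the spread between samples. Variants that alter CHG sites of the same tiles too were not tested and stay open. Reads of other copies stay open: 24.3% of called tiles had a depth ratio between the lines off by over 2 times, against 19.2% of all tested tiles, which decides neither way under a bound that was reworded after this value was seen; the first wording, within 1.5 times, would have argued against this explanation. The lines also differ in their library code series, so a batch cannot be told apart from the line, and a heritable difference in methylation stays an untested candidate explanation.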

How the results depend on the processing

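The second prior, equal weights over shared windows, the settings without deep tiles and without tiles of high CHH, and the tests of them were chosen only after the results were seen, and the others were fixed before. Of the 24 differences of levels in CHG-methylated tiles, all kept their sign with classes from leaves alone, without deep tiles and without tiles of high CHH. For counts, 27 of 27 counts stayed within 1.5 times without the tiles of high CHH, but the balance of higher and lower CHH calls of K2 heat turned. The settings below moved a count by over 1.5 times. Smaller samples, and fewer or more tiles or calls, follow from some settings by construction, and other causes were not tested. Leaving out either embryo library takes the spread between embryos out of the shared dispersion. Comparisons without embryos therefore gave equal counts for both omissions. Thinning all samples to the total calls of the shallowest moved 14 of 27 counts, of which CHH of K2 heat and of the line comparison grew and the others shrank, so depth limits most of these counts but not all. Named tiles, refitted with 1 library left out as chosen after seeing the data, lost their call in 67 of 336 refits without a library of the groups compared, which concerned 40 of 96 tiles, and in 0 of 888 without another library, and no difference changed its sign.

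The prior from well-covered tiles gave in CG 196 (late microspores against leaves), 400 (K2 heat), 0 (49CX heat) and 381 (heat by line). In CHG 1041 (late microspores against leaves), 212 (pollen against late microspores), 19 (K2 heat), 0 (49CX heat), 568 (embryos against late microspores), 1531 (embryos against heat-treated microspores), 364 (line) and 23 (heat by line). In CHH 717 (late microspores against leaves), 625 (pollen against late microspores), 11 (K2 heat), 6 (49CX heat), 2015 (embryos against late microspores), 561 (embryos against heat-treated microspores), 549 (embryos against leaves), 35 (line) and 46 (heat by line). Double the coverage minimum gave in CG 169 (late microspores against leaves), 388 (pollen against late microspores), 14 (49CX heat), 788 (embryos against late microspores), 440 (embryos against leaves) and 1163 (line). In CHG 2363 (embryos against leaves). In CHH 1151 (late microspores against leaves), 920 (pollen against late microspores), 1.0e+02 (rounded to 2 digits) (K2 heat), 116 (49CX heat), 2584 (embryos against late microspores), 1503 (embryos against heat-treated microspores), 668 (embryos against leaves), 218 (line) and 172 (heat by line). At the lower minimum, the counts were in CHH 1091 (K2 heat), 1920 (49CX heat), 2774 (embryos against leaves), 1712 (line) and 1534 (heat by line). Tiles of 1000 bp gave in CHH 1311 (late microspores against leaves), 747 (pollen against late microspores), 47 (K2 heat), 60 (49CX heat), 2379 (embryos against late microspores), 1181 (embryos against heat-treated microspores), 623 (embryos against leaves), 130 (line) and 91 (heat by line). Only the groups compared in the fit gave in CG 102 (49CX heat). In CHG 219 (49CX heat), 1359 (embryos against heat-treated microspores) and 659 (heat by line). In CHH 1631 (K2 heat), 2638 (49CX heat), 2240 (embryos against heat-treated microspores), 2184 (line) and 1977 (heat by line). Thinning gave in CG 1 (49CX heat), 826 (embryos against late microspores), 1156 (embryos against heat-treated microspores), 538 (embryos against leaves) and 1100 (line). In CHG 0 (49CX heat), 632 (embryos against late microspores), 1526 (embryos against heat-treated microspores), 2432 (embryos against leaves), 455 (line) and 134 (heat by line). In CHH 980 (K2 heat), 1181 (embryos against leaves) and 1332 (line). For 0 calls in 49CX heat, 9099 of 189376 CG and 13130 of 202867 CHG tiles had an unadjusted p under 0.05 in limma's moderated test with the second prior. After thinning, 8356 CHG tiles did. The shallower file set of the heat-treated sample gave in CG 194 (K2 heat), 727 (embryos against heat-treated microspores) and 338 (heat by line). In CHG 35 (K2 heat), 765 (embryos against heat-treated microspores) and 216 (heat by line). In CHH 27 (K2 heat), 110 (embryos against heat-treated microspores) and 173 (heat by line). The sum of both sets kept all 9 counts within 1.5 times. Without deep tiles, 344 CG tiles were called in pollen against late microspores, and the other 26 counts stayed within 1.5 times.

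Deviations of samples with the same replicate number correlated over tiles from -0.0664 to 0.119. Such deviations also hold the noise of the calls, so these values do not show whether samples of 1 number were paired. A replicate block gave in CHH 1237 (K2 heat), 2138 (49CX heat), 1767 (line) and 1214 (heat by line). It left the other 23 counts within 1.5 times. The replicate block with the second prior gave in CG 193 (late microspores against leaves), 2 (49CX heat) and 332 (heat by line). In CHG 341 (pollen against late microspores), 68 (K2 heat), 9 (49CX heat) and 107 (heat by line). In CHH 1479 (late microspores against leaves), 975 (pollen against late microspores), 56 (K2 heat), 62 (49CX heat), 1521 (embryos against heat-treated microspores), 737 (embryos against leaves), 122 (line) and 59 (heat by line).

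Of 224 alternative values of differences over all calls, 65 moved by over 1.5 times or reversed, as did 16 of 168 for CHG-methylated tiles; each is given with its comparison. With unweighted windows, CG was -1.69 points for embryos against late microspores, -2.24 against leaves and -1.16 between the lines, and CHG -0.503 and -1.51 for the first and last of these. With equal weights over shared windows, those values were 3.03, 1.01 and -1.01 for CG and 1.04 and -2.29 for CHG, so of these only the line's reversed there, as did CG of 49CX heat (0.543) and CHG and CHH of K2 heat (0.134 and 0.0840). Over windows covered in all samples, CG was 0.177 for 49CX heat, CHG 0.0609 for K2 heat and -0.126 between the lines, and CHH 0.124 for K2 heat. Without deep tiles CHG was -0.381 between the lines. With the shallower file set, CHH of CHG-methylated tiles was -0.0179 for K2 heat.

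With 1 replicate left out, where the lone sample of a group is taken to vary like the others, 57 of 102 counts stayed within 1.5 times where the replicate was of the groups compared and 222 of 240 where it was of another. Where 1 did not, counts ranged in CG 239 to 621 (late microspores against leaves), 584 to 947 (pollen against late microspores), 23 to 1.0e+02 (rounded to 2 digits) (49CX heat), 1147 to 2175 (embryos against late microspores), 1671 to 3039 (embryos against heat-treated microspores) and 584 to 3848 (embryos against leaves). In CHG 461 to 2330 (late microspores against leaves), 369 to 976 (pollen against late microspores), 98 to 412 (K2 heat), 28 to 202 (49CX heat), 449 to 1791 (embryos against late microspores), 2477 to 4055 (embryos against heat-treated microspores), 1639 to 10029 (embryos against leaves), 383 to 1108 (line) and 183 to 641 (heat by line). In CHH 413 to 3887 (late microspores against leaves), 684 to 2905 (pollen against late microspores), 348 to 1478 (K2 heat), 821 to 2595 (49CX heat), 1224 to 8026 (embryos against late microspores), 3223 to 8585 (embryos against heat-treated microspores), 493 to 5795 (embryos against leaves), 582 to 2067 (line) and 556 to 1919 (heat by line). Where a sign reversed, differences over all calls in points ranged in CG -2.03 to 0.398 (49CX heat). In CHG -0.183 to 0.223 (line). In CHH -0.0380 to 1.32 (embryos against leaves). Those of CHG-methylated tiles ranged in CHG -0.142 to 2.95 (embryos against late microspores) and -0.558 to 2.54 (embryos against heat-treated microspores). In CHH -0.330 to 1.31 (embryos against leaves).

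The correction for non-conversion, the gene and promoter calls and their replicate block were not run, because no organelle or spike-in windows were among those used and the gene table is of another build.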

Other observations

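All tests and selections in this part were made after the results were seen. Outside the CHG-methylated tiles, embryos differed from late microspores in CHG and CHH. In tiles of intermediate level, embryos held 8.79% ± 0.514 (SD, n = 2) CHG against 5.50% ± 0.209 (SD, n = 2) in late microspores (3.29 points, gap 0.727) and 6.20% ± 0.456 (SD, n = 2) in leaves (2.59 points, gap 0.727). In CG-only tiles, CHG was 2.75% ± 0.134 (SD, n = 2) in embryos against 2.00% ± 0.0592 (SD, n = 2) in late microspores (0.749 points, gap 0.189), and CHH 3.11% ± 0.118 (SD, n = 2) against 1.83% ± 0.117 (SD, n = 2) (1.28 points, gap 0.167). Low tiles differed by 0.220 points in CHG (gap 0.113) and 0.833 in CHH (gap 0.239), and incomplete conversion is not excluded as part of these differences. Against leaves, the differences in low tiles, 0.109 points in CHG and 0.748 in CHH, were under their gaps of 0.154 and 1.10.

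In pollen, 29 adjacent tiles at 13532001 to 13546500 of chromosome 9 were all called higher in CG, 1 of 2 runs of that length. Their CG level was 47.9% and 45.1% in the pollen samples and 1.58% to 3.23% in the other 11. Their depth was 27.5 and 24.9 times the median tile in pollen and 85.1 to 171 times elsewhere. Methylated CG calls per tile over the sample's median depth were 13.2 and 11.2 in pollen and 1.53 to 3.54 elsewhere. Whether reads from another copy of this sequence, such as one in an organelle, entered these tiles was not tested, since no genome was used here, so the higher level is not read as a gain of CG methylation.

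A set of 429 tiles had CHH of at least 50% in every sample, with means of 90.8% to 92.8%. Of the 309 with a CG level, 287 were over 70% in CG and 2 under 10%. More widely, 7728 tiles whose mean CHH exceeds CHG by 10 points held 8.17% to 13.3% of a sample's methylated CHH calls.

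A hypothesis was that the tiles with more CHH in leaves than in late microspores may be those with more CHH in embryos than in the heat-treated sample. These differences share no library. Over 53219 CHG-methylated tiles, which are not independent replicates, Pearson's r was 0.259 and Spearman's rho 0.157, above the bound of 0.1 set for it. Pearson's r was 0.175 in CHG-rich and 0.252 in CHG-poor bins. For CHG the same relation was -0.143. Features of the tiles, such as their CHH level, are a candidate explanation that was not separated from a shared change.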
